A study of Mus musculus with 2 samples.

How the data were processed

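The histone variant macroH2A1, an H2A form that carries a large extra domain, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in E14 cells, an established mouse embryonic stem cell line kept in medium with leukemia inhibitory factor. The design has 2 libraries, 1 made with an antibody against macroH2A1 and 1 made with non-specific IgG. There are no replicates, so every value below describes these libraries, and no interval or p-value covers the variation between cultures.

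The measurement is a list of peak regions that the authors deposited for the macroH2A1 library. Reads were mapped with Bowtie to the mouse build NCBIM37, also called mm9, per the submitters' processing notes. Peak names in the list begin with CCAT, the name of a peak caller that compares a ChIP library with a control library. The layout of the columns is that of the annotation package ChIPpeakAnno, and the deposited column on the kind of assignment says that each peak was given to the gene with the nearest start. The caller's version, its threshold, the control it was run with and any filter on reads are not given in the sources used here. The list gives no read count, fold enrichment or score per peak, and the depth of both libraries is unknown, so no precision per peak could be derived. No values of the IgG library itself were analysed here. The number at the end of each peak name was not used as a score in the main results, because its meaning is not stated. It was related to width across peaks (Spearman's rho = -0.60, across peaks, which are not independent replicates), with a median width of 1751 bp among the lower-numbered peaks and 1401 bp among the higher-numbered ones.

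Peak widths and distances were checked against the deposited start, end and gene coordinates and follow from them in every row. All starts and ends lie on multiples of 50 bp. The deposited signed distance runs from the gene start to the lower coordinate of the peak. Distances reported below were therefore recomputed as the gap from the gene start to the nearest base of the peak, which is 0 where the peak covers the start. Coordinates are as deposited, in mm9. Each peak has 1 assigned gene in the list, so a peak inside a long gene can be listed under a neighbour whose start is closer.

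Of the 2560 peaks, 891 (34.8%) were assigned to an Ensembl gene for which the list gives no symbol, and these could not be tested in gene lists. Of the 1408 distinct symbol entries, 1385 were matched by symbol or synonym, on the same chromosome, to the RefSeq gene table of assembly GRCm38.p6. The chromosome was required to be the same because the list gives some copies several symbols, including that of the parent gene (111 peaks have more than 1 symbol). This requirement was set after the first results of the gene lists had been seen. For 1 assigned gene the symbol had been turned into a date, and that gene was left unnamed. The gene table was used for names and for the spacing and length of genes as covariates. Its coordinates, which belong to a later build than the mm9 of the peaks, are not printed. Gene lengths in the list and in the table were closely related over 1386 genes (Spearman's rho = 0.97 across genes). The background was the 21631 protein-coding genes of chromosomes 1 to 19 and X, a restriction also set after the data were seen. A gene absent from the annotation used by the authors could not have received a peak, and such genes could not be told apart in the background.

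Lists of genes were written before the data were examined. There were 21 of them: Hox genes, other developmental transcription factors, developmental signalling ligands and receptors, pluripotency genes, cytosolic ribosomal proteins, cell cycle genes, imprinted genes, germline genes, neuronal genes, mesoderm and muscle, endoderm and liver, trophoblast, feeder or fibroblast, epidermal genes, chromatin regulators, clustered protocadherins, olfactory receptors, vomeronasal receptors, replication-dependent histones, zinc finger genes with Zfp symbols and keratins. Each was tested with a two-sided Fisher's exact test of list members with a peak against all other genes, with a conditional odds ratio, its exact 95% interval and Benjamini-Hochberg adjustment over the 21 lists at 0.05. Because a gene with a wide gap around its start collects more peaks under nearest-start assignment, each list with at least 3 members with a peak was also fitted in a logistic model with gene length and the gaps to the neighbouring genes as covariates, with Wald intervals and a likelihood-ratio test adjusted over the 11 lists so fitted. This model was added after the results of the exact tests had been seen. In 20 simulations in which only length and spacing set the chance of a peak, with 21631 genes, Fisher's test called the neuronal list above the rest in 12, the developmental transcription factors in 1 and the pluripotency list in 0. The covariate model recovered a planted odds ratio of 4 for 200 genes as 3.95 (median of 20 simulations). The simulated chances came from a fit of this same model, and the planted genes were drawn at random. The recovery therefore does not test the model where its form is wrong or where list membership goes with spacing.

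Peaks per chromosome were tested with two-sided exact binomial tests, with Benjamini-Hochberg adjustment over 20 chromosomes. The expected share came from the number of protein-coding genes, because no chromosome lengths were supplied. A second expectation used the span of each chromosome seen in the list, up to its last peak or assigned gene end, and was added after the data were seen. Distance bins around gene starts, the test of covered starts and the count of regions close to each other were also chosen after the data were seen. Position classes were given with Wilson 95% intervals. The planned comparison of peaks nearer to the start with peaks nearer to the end of their gene was left out, since assignment to the nearest start favours the start by construction. Widths were compared with a two-sided permutation test of medians (100000 resamples). Genes with 2 or more peaks were compared with 10000 random assignments of the peaks to protein-coding genes. Tests over peaks treat peaks as independent, which neighbouring peaks are not, so their p-values are too small to an unknown degree. Genes were named by a rule set before the data were examined: the 20 genes that have most peaks (taken among genes with a symbol, a restriction added after the data were seen), the 5 widest regions, from each list the members with a peak (all if 4 or fewer, otherwise the 4 with most peaks, ties by total peak length), and Pou5f1, Nanog, Sox2 and the gene of macroH2A1 itself. Not every gene that this rule selects is named below. Other genes named below were chosen after their values were seen. Alternatives were the peaks wider than the median, peaks merged within 1 kb, stricter limits on the distance to the gene, other backgrounds and covariates. Python 3.11.15, SciPy 1.17.1, statsmodels 0.14.6, pandas 2.3.3 and matplotlib 3.10.9 were used.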

Results

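The deposited list held 2560 macroH2A1 peaks in E14 mouse embryonic stem cells, from 1 macroH2A1 library beside 1 IgG library. These were 2558 distinct regions, since 2 regions were listed under more than 1 peak name. Together they covered 4.09 Mb. The median width was 1551 bp (interquartile range 1301 to 1814 bp), and the extremes were 1051 and 4551 bp. The widest region lay on chromosome 4 at 34874850 to 34879400, downstream of the start of a gene without a symbol. The next lay inside Nt5e, which encodes a cell-surface nucleotidase, on chromosome 9 at 88225950 to 88230300 (4351 bp). A region of 4151 bp lay 11.5 kb from the start of Myl10 on chromosome 5, a region of 3801 bp near a gene without a symbol on chromosome 18, and a region of 3651 bp inside Myo18b, an unconventional myosin gene, on chromosome 5.

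The first comparison concerned where macroH2A1 peaks lay relative to genes. The peaks were mostly distant from gene starts: the median distance to the start of the assigned gene was 32.2 kb, and 76.4% of peaks (1955 of 2560; 95% interval 74.7 to 78.0%) lay more than 10 kb away. A gene start was covered by 30 peaks (1.17%, 0.82 to 1.67%), and 114 (4.45%, 3.72 to 5.32%) lay within 1 kb of it. No random expectation is given for these distances. For covered starts 1 is given below, and random placement was not excluded. Of the 30, 16 were at genes with a symbol, among them Pgk1 (a glycolytic enzyme), Cacna1i (a calcium channel subunit), Prx, Tmem117, Selplg and Cxcl11, named here after their values were seen. In the authors' classes, 51.4% of peaks (1316; 49.5 to 53.3%) were upstream of their gene, 32.6% (834; 30.8 to 34.4%) downstream and 14.2% (364; 12.9 to 15.6%) inside it. Overlaps with a gene's start, its end or the whole gene made up 19, 16 and 11 peaks.

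Upstream peaks outnumbered downstream peaks (1316 against 834, 61.2% upstream, exact binomial p = 2.07e-25), but the downstream class leaves out peaks inside the gene. A peak past the gene end is also at least a gene length from its assigned start, so nearest-start assignment favours the upstream class. A p-value against an equal split therefore cannot show a preference. At genes without a symbol the numbers were 433 and 424 (50.5%). Counted instead by the side of the gene start on which the midpoint lay, 52.0% of peaks (1332 against 1228; 50.1 to 54.0%) were upstream, with an exact binomial p = 0.042. The upstream excess by midpoint was seen at genes with a symbol and depended on distance. Within 2 kb of the start of such genes, 58 midpoints lay upstream and 26 downstream (69.0%, 58.5 to 77.9%; exact binomial test, adjusted p = 0.0025 over 12 tests in 6 distance bins). From 2 to 5 kb (88 and 60, adjusted exact p = 0.063) and from 5 to 10 kb (99 and 74, adjusted exact p = 0.135) the difference did not pass. Within 10 kb, a bin that joins these 3, the numbers were 245 and 160 (60.5%, adjusted exact p = 0.00025). From 10 to 50 kb they were 390 and 283 (57.9%, adjusted exact p = 0.00025), and from 50 to 200 kb the order was the other way, 201 and 268 (42.9%, adjusted exact p = 0.0068). For genes without a symbol the numbers within 10 kb were 85 and 82 (adjusted exact p = 0.96). The distance bins were chosen after the data were seen. These tests also assume an equal split. The stretch nearest to a gene start need not be equally long on both sides, since the gene itself lies downstream.

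**Figure D1:**
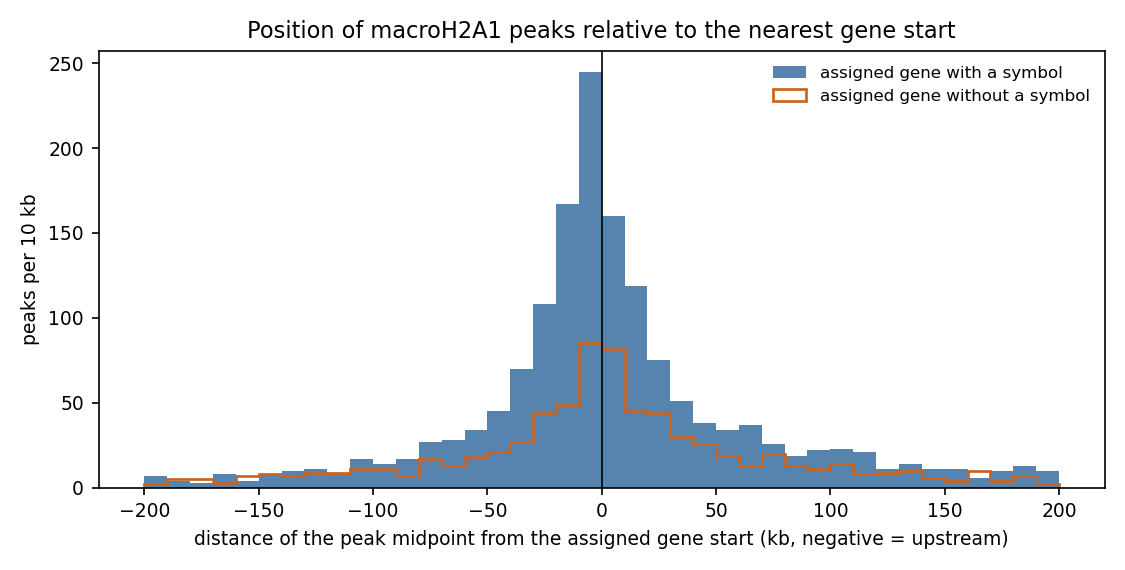
Number of peaks per 10 kb (vertical axis) by the distance of the peak midpoint from the start of the assigned gene in kb (horizontal axis, negative values upstream), for genes with a symbol (filled) and without (line), leaving out 278 peaks farther than 200 kb. At genes with a symbol, 245 peaks lie in the 10 kb upstream of the start and 160 in the 10 kb downstream.

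The second comparison asked which kinds of genes carried peaks. Of 21631 protein-coding genes, 1323 (6.12%) had at least 1 assigned peak that could be matched by symbol. The 723 assigned genes without a symbol could not be counted. Any protein-coding gene of the background among them stood as a gene without a peak. This lowers the share of other genes with a peak and can raise the odds ratios of lists of named genes, by an unknown amount. Of the 21 lists, 5 carried peaks more often than other genes and 2 less often (Fisher's exact test, Benjamini-Hochberg adjusted over the 21 lists). In a model with gene length and gaps to neighbours as covariates, added after these results were seen, 2 of the 6 of these lists that were fitted were called, the pluripotency genes and the developmental transcription factors.

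Pluripotency genes had the highest odds ratio. Of 39 members, 11 had a peak (28.2% against 6.08% of other genes), an odds ratio of 6.07 (95% interval 2.72 to 12.6; Fisher's exact test, adjusted p = 7.7e-05) and of 4.97 (2.39 to 10.4) with the covariates. Tcf7l1, the Wnt pathway repressor known as Tcf3 in stem cells, had 2 peaks upstream, the closer 3.15 kb from its start. Mycn had 2 upstream peaks, at 3.31 and 69.6 kb. Lefty1 and Lefty2, neighbouring genes for inhibitors of Nodal signalling, each had 1, the first 3.24 kb upstream of Lefty1 (chromosome 1, 182859700 to 182861950) and the second inside Lefty2, 2.21 kb from its start (182825450 to 182827200). The other members with a peak were Sox2, Nr5a2, Stat3, Tbx3, Jarid2, Il6st and Tfcp2l1. Over the 13 peaks of the list the median distance was 31.2 kb, and 4 peaks lay within 5 kb of the gene start. Tbx3, Lefty1, Lefty2 and Jarid2 also belong to other lists. The Sox2 peak was distant, 152 kb downstream on chromosome 3 (34700450 to 34702200). No peak was assigned to Pou5f1 or Nanog, the other core pluripotency factors, nor to H2afy, the gene of macroH2A1.

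Developmental transcription factors other than Hox genes carried peaks at 36 of 180 genes (20.0% against 6.00% of other genes), an odds ratio of 3.92 (2.63 to 5.70; Fisher's exact test, adjusted p = 2.47e-09) and of 2.90 (1.97 to 4.26) with the covariates. Tbx5, a regulator of heart and forelimb development, had 5 peaks spread over chromosome 5 from 120202300 to 120342300, of which 3 lay inside the gene. Uncx, a homeobox gene of the axial skeleton, had 4, of which 3 were downstream. Pax7, a muscle and neural crest regulator, had 3, and Lhx5, a forebrain LIM-homeobox gene, had 2 upstream peaks. The others included Otx2, Sox1, Sox11, Pax2, Pax3, En1, Neurog1, Neurog2, Foxf1, Six6, Tfap2c, Tbx3 and T. These 36 genes had 51 peaks, none covering the gene start and 8 within 5 kb of it, with a median distance of 21.9 kb. Among Hox genes, 2 of 39 had a peak (5.13%, odds ratio 0.83, 0.10 to 3.22; Fisher's exact test, adjusted p = 1). They were Hoxb13, with 2 peaks flanking the gene, and Hoxa13, with 1 peak 2.40 kb from its start. Both lie at the end of their cluster. The Hox list had too few members with a peak for the covariate model. Its odds ratio was 1.64 (0.19 to 6.38) among wider peaks and 4.73 (0.55 to 18.5) within 5 kb of the gene start. Neither was called, and these wide intervals leave open whether Hox genes carry more or fewer peaks than other genes.

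The list of developmental signalling genes had peaks at 15 of 97 genes (15.5%), an odds ratio of 2.83 (1.51 to 4.96; Fisher's exact test, adjusted p = 0.0028), against 2.12 (1.19 to 3.76; likelihood-ratio test, adjusted p = 0.064) with the covariates. It was named for ligands and receptors but holds other pathway members too, such as the transcription factor Gli2. Bmp7, Wnt7b and Fzd7 had 2 peaks each, and Wnt8a had 2, of which 1 began 0.38 kb past its start. Further members included Dkk1, Fgfr1, Shh, Ptch1, Gli2, Sfrp1, Fgf13 and Fgf18, and Lefty1 and Lefty2 belong to this list as well. Counting only peaks within 5 kb of a gene start, these 3 lists were called: 8 developmental transcription factors (odds ratio 4.15), 6 signalling genes (5.85) and 4 pluripotency genes (10.1), each with an adjusted p of 0.0076 by Fisher's exact test. The neighbouring genes Lefty1 and Lefty2 are counted in both the signalling and the pluripotency genes here, so those calls are not independent. Gene length and gaps were not covariates in this setting. With peaks overlapping the gene (7, 4 and 1 genes) or within 1 kb of its start (1, 2 and 0 genes), none of the 3 lists was called.

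Neuronal genes had peaks at 14 of 76 members (18.4%, odds ratio 3.49, 1.80 to 6.33; Fisher's exact test, adjusted p = 0.00078), and with the covariates the odds ratio was 1.10 (0.59 to 2.05). Opcml, Grin2a and Csmd1 had 3 peaks each and Nrg1 had 2. The 3 peaks of Opcml and the 3 of Grin2a all lay inside the genes, the closest 522 kb from the start of Opcml and 174 kb from that of Grin2a. Feeder or fibroblast genes passed narrowly, at 5 of 24 (Twist2, Vim, Thy1, Col3a1 and Pdgfra; odds ratio 4.05, 1.18 to 11.2; Fisher's exact test, adjusted p = 0.041), and not with the covariates (2.71, 0.98 to 7.46).

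Olfactory receptor genes carried fewer peaks, 19 of 1110 (1.71%, odds ratio 0.26, 0.15 to 0.40; Fisher's exact test, adjusted p = 9.76e-12), among them Olfr1339, Olfr279, Olfr1024 and Olfr15. Vomeronasal receptor genes had 2 of 360, Vmn2r10 and Vmn2r89 (0.56%, odds ratio 0.084, 0.010 to 0.31; Fisher's exact test, adjusted p = 5.8e-07). With the covariates the olfactory odds ratio was 0.67 (0.41 to 1.11). The vomeronasal list had too few members with a peak for that model.

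The remaining lists did not pass the test. No germline gene (0 of 46, which allows a share of up to 6.52%), no trophoblast gene (0 of 18, up to 16.7%) and no replication-dependent histone gene (0 of 71, up to 4.23%; Fisher's exact test, adjusted p = 0.058) had a peak. Ribosomal protein genes had 1 of 79, Rps26, and 4 of 79 when symbols were matched to genes on any chromosome. Cell cycle genes had 2 of 45: Cdkn1a, the inhibitor p21, with a peak 2.37 kb upstream of its start, and E2f1. Imprinted genes had 4 of 40 (Kcnk9, Dlk1, Ppp1r9a and Mkrn3), and chromatin regulators 4 of 50, among them Cbx8, Chd1 and Jarid2. Mesoderm and muscle genes had 4 of 24 (Meox1, Myl2, Flt1 and Cdh5; Fisher's exact test, adjusted p = 0.13), endoderm and liver genes 3 of 23 (Fgg and Cxcr4 among them), epidermal genes 1 of 25 (Trp63), clustered protocadherins 2 of 60 (Pcdha6 and Pcdhb5), keratins 2 of 53 (Krt9 and Krt26) and Zfp genes 18 of 397, with Zfp217, Zfp536, Zfp952 and Zfp423 first.

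**Figure D2:**
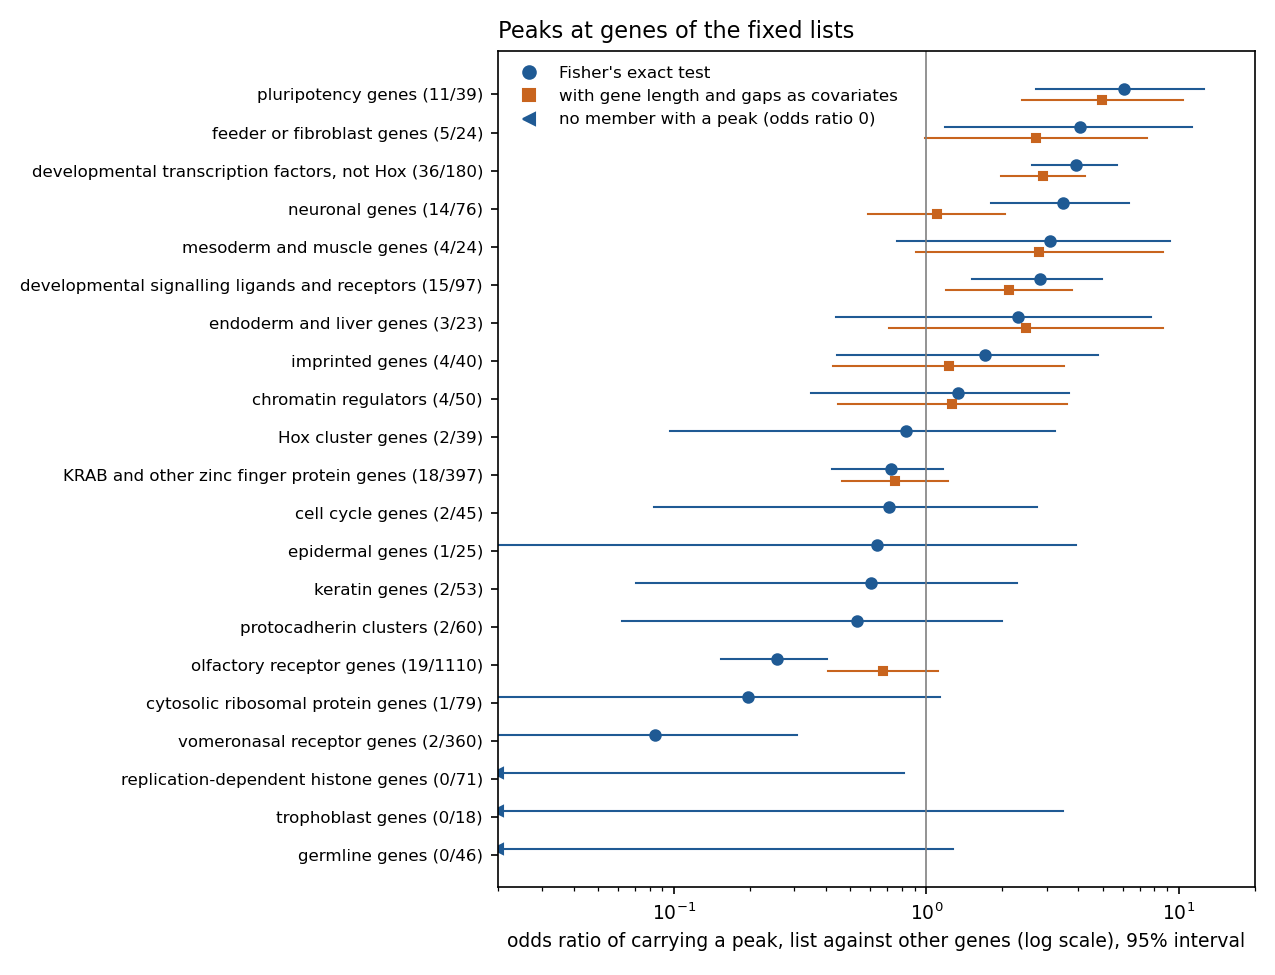
Odds ratio of carrying a macroH2A1 peak, list members against other protein-coding genes (horizontal axis, log scale, with 95% intervals), for the 21 lists, with the number of members with a peak over the number of members; circles are from Fisher's exact test, squares from the model with gene length and gaps, triangles at the left edge are lists without a peak, and 3 intervals run off that edge. Pluripotency genes (6.07 and 4.97) and developmental transcription factors (3.92 and 2.90) stay to the right of 1 in both, while neuronal genes move from 3.49 to 1.10.

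Peaks at developmental transcription factor genes, Hox genes included, were slightly wider than other peaks. The median width was 1726 bp over 54 peaks and 1551 bp over 2506 others, a difference of 175 bp (two-sided permutation test of medians, p = 0.013). Among the peaks wider than the median of the list the difference was 25 bp and did not pass (permutation p = 0.79).

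Some genes had several peaks. Of the protein-coding genes, 184 had 2 or more peaks, against 53.8 on average (95% of values from 41 to 68, the highest of 10000 being 82) when the peaks were assigned at random with equal chance per gene. With chances in proportion to gene length the random mean was 186 (167 to 205), and with chances from the model of gene length and gaps it was 89.9 (74 to 107). The observed 184 thus lay above the other ranges but within that by gene length, under which there was no excess. Among genes with a symbol, those with most peaks were Sez6l, a neuronal membrane protein gene, with 6 peaks (5 upstream and 1 inside), and Ajap1, a junction protein gene, with 6. Tbx5 and Elfn1 had 5 each, those of Elfn1 all inside the gene. Eln, the elastin gene, Insig1, a regulator of sterol synthesis, Uncx, Ttc29, Ttll7, 1700029F12Rik, 5830454E08Rik and Gm5420 had 4 each. A further 30 genes had 3 each, of which the 8 with the greatest total peak length were Nt5e (with 1 region listed again), Ntrk2, Cmas, Sulf2, Tmem132c, Tnfrsf19, Anks1b and Arl15.

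A dense run of peaks lay on chromosome 5 near the T-box genes Tbx3 and Tbx5. Between the end of Med13l and the start of Tbx3, a wide gap between genes, there were 11 peaks. The 9 assigned to ENSMUSG00000084548, a gene without a symbol, were the most for any gene in the list, and 8 of them fell within 103 kb (119753550 to 119856050). A single peak was assigned to Tbx3, 101 kb upstream of its start. The gene lists count Tbx3 with 1 peak and none of these 9.

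**Figure D3:**
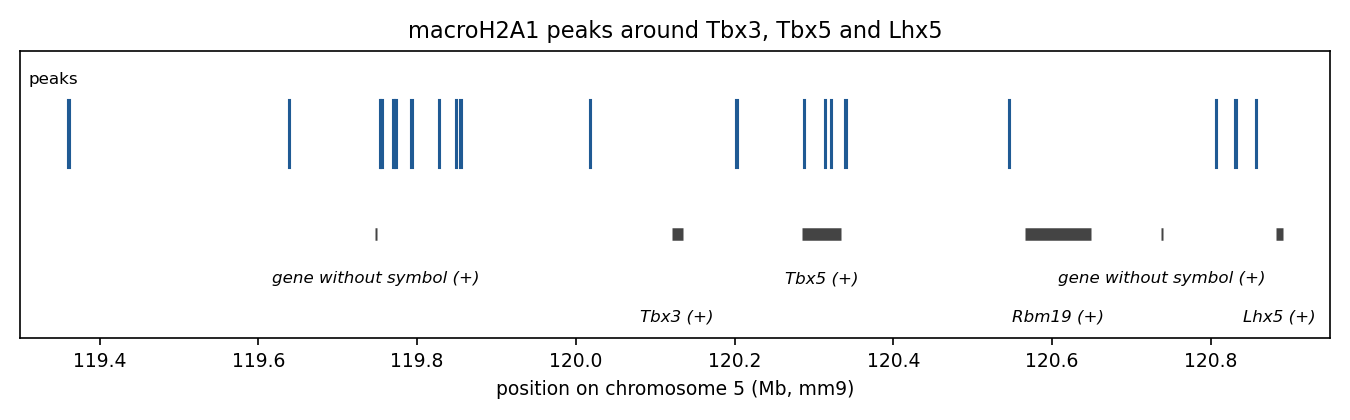
Map of chromosome 5 (mm9, horizontal axis in Mb) with macroH2A1 peaks as blue bars, to scale in width, and the assigned genes as grey bars with their strand. The 20 peaks of the window include 8 between 119753550 and 119856050 and 5 at Tbx5.

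The third comparison concerned the chromosomes. Chromosome X had the fewest peaks, 26, against 114 expected from its protein-coding genes (ratio 0.23, 95% interval 0.15 to 0.33, exact binomial test, adjusted p = 1.74e-22) and 155 expected from its span (ratio 0.17). E14 cells are male and have a single X chromosome. Chromosome 5 had the most, 250, a ratio of 1.66 by genes (1.47 to 1.87, exact binomial test, adjusted p = 8.49e-14) and 1.64 by span (1.45 to 1.84). Chromosomes 8 (178 peaks, ratios 1.44 and 1.37) and 10 (165 peaks, 1.39 and 1.26) were above and chromosome 7 (108 peaks, 0.45 and 0.71) below both expectations. In all, 13 of 20 chromosomes differed from the share of genes and 6 from the share of span. Chromosomes 1, 3, 11, 12 and 17, which differed by genes, lay on the other side of 1 by span and did not pass there.

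**Figure D4:**
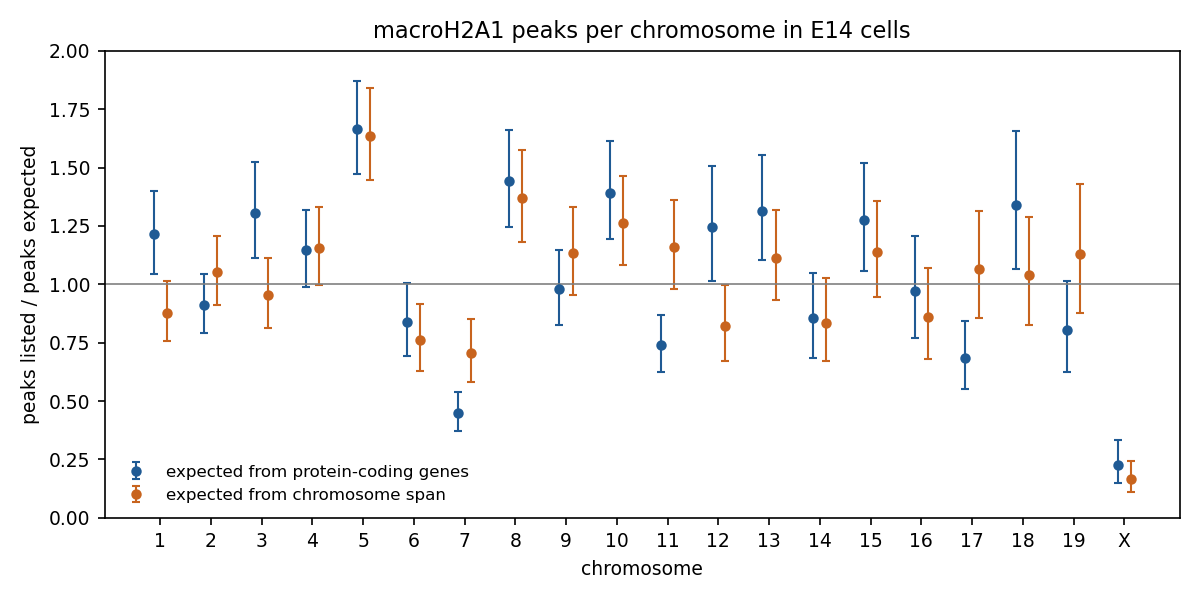
Ratio of listed to expected macroH2A1 peaks (vertical axis) for each chromosome (horizontal axis), with the expectation from protein-coding genes (blue) or from the chromosome span seen in the list (orange) and exact binomial 95% intervals for counting error. Chromosome 5 is highest (1.66 and 1.64) and chromosome X lowest (0.23 and 0.17).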

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

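Chosen only after results were seen were the expectation from chromosome span, the model with gene length and gaps, symbols matched on any chromosome, and the settings without chromosome 5, without the region from Med13l to Lhx5, by peak number, by genes with or without a symbol and by midpoint. The ratios of chromosomes 5 (1.54 to 1.81) and X (0.17 to 0.25) had the same direction and passed the threshold in each of their 4 alternatives. The share of upstream peaks did so in 4 of 5 (52.0% to 68.3%) and not at genes without a symbol (50.5%). Each of these settings was tested against an equal split, which assignment to the nearest start need not give. Among the peaks wider than the median (1243 peaks), and also with the span expectation, 6 chromosomes differed instead of 13. Of the 13 chromosomes called by genes, 5 crossed 1 with the span, to 0.88 for chromosome 1, 0.95 for chromosome 3, 1.16 for chromosome 11, 0.82 for chromosome 12 and 1.07 for chromosome 17, and the cause was not tested. Of the gene lists, 7 were called with all peaks and 7, the same ones, with symbols matched on any chromosome, where ribosomal protein genes with a peak rose from 1 to 4. The number was 2 with peaks overlapping the gene (neuronal genes and olfactory receptors), 3 within 5 kb of the gene start, 3 with gene length as covariate and 2 with length and gaps. It was 0 within 1 kb, where 1 list, the signalling genes, had an unadjusted p under 0.05 by Fisher's exact test. Within 1 kb the odds ratio was 1.90 for developmental transcription factors (1 gene), 7.29 for signalling genes (2 genes), 0.91 for olfactory receptors, and 0 for pluripotency, neuronal, fibroblast and vomeronasal genes, which had no peak there. With peaks overlapping the gene, it was 2.61 for developmental transcription factors, 2.76 for signalling genes, 1.68 for pluripotency genes, and 0 for fibroblast and vomeronasal genes, none of them called. Within 5 kb it was 1.16 for neuronal genes, 0.70 for olfactory receptors and 0 for fibroblast and vomeronasal genes. With gene length as covariate, neuronal genes had 1.38, olfactory receptors 0.76 and fibroblast genes 3.98, and with length and gaps signalling genes had 2.12, neuronal genes 1.10, fibroblast genes 2.71 and olfactory receptors 0.67, all past the threshold before and not after. Fibroblast genes also lost the call among wider peaks (2.76), among lower-numbered peaks (1.33) and without chromosome 5 (3.34), and olfactory receptors against all gene types (0.60). That background gained mesoderm and muscle genes (6.97) and raised the odds ratios of developmental transcription factors to 8.90, signalling genes to 6.42, pluripotency genes to 13.8, neuronal genes to 7.92 and fibroblast genes to 9.18. It adds genes of other types, at which few peaks were matched: 1563 of the 1641 matched peaks were at protein-coding genes. Higher odds ratios for lists of protein-coding genes therefore follow by construction and lend those lists no support. The width difference was 25 bp among wider peaks (permutation p = 0.79), a setting that narrows the range of widths by construction. The ratio of genes with several peaks to the random mean, 3.42, was 0.99 with chances by gene length. An expectation from assembled chromosome lengths was not run, since none were supplied, and with 1 gene per peak in the list, taking the closest pair removed only regions listed again. Without counts or a score, a gene without a peak was not separable from a gene below the caller's threshold.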

Other observations

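The ratio of chromosome X to its share of genes was planned, but its use to weigh an explanation was set after its value was seen. The other tests in this part were chosen after the counts per chromosome, the unadjusted list results and the positions of the peaks had been seen. The odds ratios with covariates had not been seen when their test was set. Apart from the T-box region, the list held 4 further runs of at least 6 regions with gaps of no more than 100 kb. The one with most regions had 9 over 260 kb of chromosome 5 (112835600 to 113095100), assigned to Asphd2, Gm6588 and Sez6l. A run of 8 spanned 296 kb of chromosome 4 (139241400 to 139537500) from Tas1r2, a sweet taste receptor gene, over Pax7 to Klhdc7a. Runs of 7 lay on chromosome 9 (120456500 to 120622500, at Entpd3 and 5830454E08Rik) and on chromosome 5 (111908200 to 112239350, at Mn1 and a gene without a symbol). Of the 5 runs, 3 were on chromosome 5. Across the genome 531 of 2558 regions (20.8%) had another within 50 kb, against 212 to 363 in 1000 random placements along the chromosomes. Peaks covered the start of 15 protein-coding genes, against 34.8 expected if the same covered length were placed at random over the chromosome span (ratio 0.43, 95% interval 0.24 to 0.71). A further 14 peaks covered the start of genes without a symbol, whose type is not known, and 9 of these peaks covered the whole gene. With all 14 counted as protein-coding, an upper limit, the number was 29 (ratio 0.83, 0.56 to 1.20). Random placement relative to gene starts was therefore not excluded.

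The preference for pluripotency and developmental genes could come from the assignment to the nearest start, which gives more peaks to genes in wide gaps. The odds ratio with length and gaps as covariates argues against length and gaps, as measured here, as the whole cause for pluripotency genes (4.97, 2.39 to 10.4) and developmental transcription factors (2.90, 1.97 to 4.26). For signalling genes it moved from 2.83 (1.51 to 4.96) to 2.12 (1.19 to 3.76), an interval above 1, but the call ended because the smaller effect missed the threshold after adjustment over 11 lists. For neuronal genes it fell to 1.10 (0.59 to 2.05) and for olfactory receptors it moved to 0.67 (0.41 to 1.11), so length and spacing could account for those 2 lists. The gaps ran between gene edges in the later gene table, not between the gene starts used for the assignment. A remaining effect of the assignment was therefore not excluded for any list. Neither was an effect of the assigned genes without a symbol, which could not be counted. GC content and mappability were not tested, and no biological explanation was tested, since the design has no second group of cells.

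Chromosome X carried 0.23 times the peaks expected from its genes (interval 0.15 to 0.33), so a low gene number alone would not give so few peaks. This is the ratio reported above and not a separate test. A single X copy in male cells would lower the reads there and may drop weak regions below the caller's threshold. That would leave relatively more of the wide regions, and the share on X was 1.13% (14 of 1243) among wider peaks and 0.91% (12 of 1317) among the rest, which is that direction. The odds ratio of 1.24 has an interval from 0.53 to 2.94, so with 26 peaks an effect of copy number and other causes cannot be told apart. No biological explanation was tested here either.

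The peak over the start of Pgk1 is number 6 in the list and 2301 bp wide (chromosome X, 103381200 to 103383500), on the chromosome with the fewest peaks. Its midpoint lies upstream of the gene start (-196 bp). The Pgk1 promoter is a common part of vectors for drug selection, and DNA from such a vector could map there, but a peak of the chromosomal gene would lie at the same place, so the 2 cannot be told apart without reads.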
